A study of Mus musculus with 10 samples.

How the data were processed

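RNA was extracted from LNCaP xenograft tumours with TRIzol and sequenced on an Illumina platform, per the labels' protocols. The submitters' processing notes name fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and GATK 4.1.1.0 with genome build hg38, without giving their roles or settings. Strandedness, the annotation release and any removal of mouse reads are not given in the sources used here. The sample labels give the organism as mouse, whereas the deposited tables hold human Ensembl genes, so the values describe reads assigned to the human genome.

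The deposited count table holds raw read counts per gene for the 10 libraries, per the file headers and the whole-number values. The deposited FPKM values equal the count divided by gene length and by 1 total per library, and this total exceeded the sum of counts by a factor constant over the genes of a library. The total was a whole number, within 0.001 reads, in 0 of 10 libraries, so it is no count of reads. Its ratio to the count total had an SD of 0.09 on the log2 scale over libraries, and 0.01 after division by the DESeq2 size factor per count, so the ratio was treated as a scaling factor of unknown making, which is not given in the sources used here. A deposited table of group mean FPKM by the authors equalled the mean of the 5 libraries for the IL-15 group but differed from it in 38579 genes for the control group, and was not used further. In 0 genes was 6 times this control mean under the sum of the 5 control libraries, so a mean over 6 libraries is not excluded, and the 5 control libraries could be part of a larger group. Gene coordinates are those of the deposited count table (hg38). The mouse annotation at hand was used only to look up symbols.

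Groups were taken from the sample labels, with 5 libraries each. The labels imply a mouse per tumour without stating it and do not say how many donors provided the cells, so p-values measure the spread between these libraries. No 2 libraries agreed within sampling noise (chi-square per degree of freedom from 20.4 to 90.3 over 45 pairs). Genes were kept with edgeR's filterByExpr (minimum count 10), leaving 16913, scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood test (robust fit, R 4.3.3) at a Benjamini-Hochberg adjusted p of 0.05. The common biological coefficient of variation was 0.306. Before the data were examined, 40 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members (34) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. For 12 cell type lists, log2 of the summed CPM (pseudocount 0.1 CPM) was compared by a two-sided exact permutation test over all 252 assignments of 5 against 5 libraries. Principal components used log2 CPM with a prior count of 2 for 500 genes. Correlations used 100000 permutations.

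The rule for named genes took, since none passed the threshold, the 10 protein-coding genes with the smallest p per direction and a mean of at least 1 CPM, up to 4 members with the smallest p of each list described, and a fixed set of prostate, immune and MHC genes. Some genes that the rule takes are not reported here. Y-linked genes and XIST were left out of all gene tables. Of the list symbols, 2 were matched under a former symbol (ACPP for ACP3) and 1 was not found.

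On simulated counts drawn from the means, library sizes and dispersions of these libraries for this comparison, with 100 genes changed 2-fold and 100 changed 4-fold among 16567 tested genes, edgeR recovered 33% of the 2-fold and 93% of the 4-fold changes with 4 false calls, and camera called 0 of 34 unchanged lists. The simulated genes were drawn independently, so the camera result says nothing on lists whose members vary together. The changed genes were picked at random from the tested genes and shared no variation between libraries. Their recovery therefore need not hold for scarce, variable genes. In the real data GZMA, with a log2 fold change of 3.42, was not called by edgeR (adjusted p = 0.758). The real ribosomal protein and NK cell lists had estimated correlations of 0.894 and 0.719. Alternatives covered the scaling, the low-count filter, biotype, DESeq2 1.42.0, limma, FPKM in place of counts, the replicate number as a block, and each library left out in turn. Covariates for the ratio of FPKM total to count total, for the pan-leukocyte sum and for the T cell sum, a pseudocount of 1 CPM and the restriction to scarce markers were added after the data had been seen.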

Results

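The series profiled RNA from subcutaneous tumours of LNCaP, an androgen-sensitive human prostate cancer cell line, grown in NSG mice, a strain without its own T, B or NK cells. Tumour-bearing mice received weekly intraperitoneal injections of sipuleucel-T (sip-T), a cell product prepared from human blood cells cultured with a fusion of prostatic acid phosphatase and GM-CSF, in a volume of 100 µl per injection. The 5 control tumours came from mice given control sip-T, and the 5 IL-15 tumours from mice given sip-T with 1 µg of recombinant human IL-15, a cytokine that sustains T and NK cells. The design text speaks of IL-15 treated cells and of injected IL-15, whereas the sample labels name control sip-T with IL-15, so the comparison cannot separate treatment of the cells from injection. Tumours were taken on day 7 after the last injection. The authors' control group mean did not equal that of the 5 control libraries, which could therefore be part of a larger group. The count table held 58735 human genes, of which 17801 had no count in any library. Total counts, in units of 1e+06 reads, were 15.6 ± 1.15 in control libraries and 15.03 ± 2.44 in IL-15 libraries (SD, n = 5 each), with a range of 13.6 to 19.3. A floor of 3 counts corresponded to 0.155 to 0.221 CPM (counts per 1e+06 counts), for counting error only. All errors on CPM values below are SD over 5 libraries and all errors on log2 fold changes, which are edgeR's, are standard errors.

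The comparison of IL-15 with control tumours asked which tumour and leukocyte transcripts differed when sip-T was given with IL-15. Transcripts of human T cells and of cytotoxic lymphocytes had higher means in IL-15 tumours, but the difference did not pass the test of the spread between tumours. The summed T cell list of 24 genes stood at 11.6 ± 8.35 CPM in control and 30.4 ± 21.6 CPM in IL-15 tumours, a 2.35-fold difference in geometric mean (log2 difference 1.23 ± 0.66, n = 5 per group), with p = 0.0714 in a two-sided exact permutation test and 0.238 after adjustment over 12 cell type lists. The summed NK cell and cytotoxicity list of 26 genes stood at 9.85 ± 8.86 and 27.96 ± 20.7 CPM (log2 difference 1.47 ± 0.76, n = 5 per group, exact permutation p = 0.0794, adjusted 0.238). The smallest p this design allows is 0.00794 before adjustment, and a lone list at that value would not pass after adjustment over the 12 lists. IL-15 tumours 1, 3 and 4 held 60.9, 37.9 and 34.3 CPM of T cell transcripts, whereas IL-15 tumours 2 and 5, with 8.13 and 11.03 CPM, lay within the control range of 6.40 to 26.4 CPM.

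Among the 7 cytotoxicity genes abundant enough for the edgeR test, every fold change was above 0, with a median log2 fold change of 1.25. GZMA, which encodes granzyme A (ENSG00000145649, chromosome 5, 55102648 to 55110252 on hg38), measured 0.189 ± 0.355 CPM in control tumours and 2.09 ± 1.49 CPM in IL-15 tumours (log2 fold change 3.42 ± 0.89, edgeR adjusted p = 0.758 over all genes). It passed DESeq2 (adjusted p = 0.0485) and was the 1 member past 0.05 when edgeR p-values were adjusted over the list alone (0.0161). The edgeR call was lost without control replicate 1 or 4 or IL-15 replicate 1 or 3, with values up to 0.0650. The pore-forming protein gene PRF1 measured 0.516 ± 0.791 against 2.51 ± 1.70 CPM and the granulysin gene GNLY 2.04 ± 2.48 against 7.31 ± 5.76 CPM, neither past a threshold. All 5 tested T cell genes also had fold changes above 0, with CD8A, the coreceptor of cytotoxic T cells, at 1.59 ± 1.49 against 6.18 ± 4.28 CPM (log2 fold change 1.95 ± 0.65) and ZAP70, a T cell receptor kinase, at 0.642 ± 0.421 against 2.27 ± 2.12 CPM. CD3E, PTPRC, GZMB and IL2RB, the gene of a receptor subunit for IL-15, were too scarce to be tested. Their totals over 5 libraries were 19, 54, 42 and 42 counts in control and 81, 192, 231 and 180 counts in IL-15 tumours. IL15 itself had 10 and 9 counts.

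In the camera test with a preset correlation of 0.01, both lists lay above other genes (adjusted p = 1.89e-04 for NK cell and cytotoxicity, 0.0308 for T cell), and neither call held with an estimated correlation (adjusted p = 0.744 with an estimated correlation for each). The pan-leukocyte list behaved likewise (median log2 fold change 1.07 over 5 tested genes, camera adjusted p = 0.0308, and adjusted p = 0.744 with an estimated correlation). Its sum, 261 ± 180 against 549 ± 225 CPM (exact permutation p = 0.0556, adjusted 0.238, n = 5 per group), consisted to 94.2% of LCP1, an actin-bundling protein gene that epithelial tumour cells also express. Summed B cell and plasma cell genes (19.7 ± 5.24 against 20.4 ± 2.98 CPM) and monocyte, macrophage and dendritic cell genes (6.62 ± 1.78 against 6.22 ± 0.95 CPM) had log2 differences of 0.09 and -0.06, with adjusted exact permutation p = 0.892 for each (n = 5 per group). Over members with a mean under 1 CPM over all libraries, a choice made after the data were seen, the B cell difference was -0.97 (exact permutation p = 0.0317, adjusted 0.167), the pan-leukocyte difference 2.44 (exact permutation p = 0.0476, adjusted 0.167) and the NK cell difference 0.73 (exact permutation p = 0.222, adjusted 0.50).

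**Figure D1:**
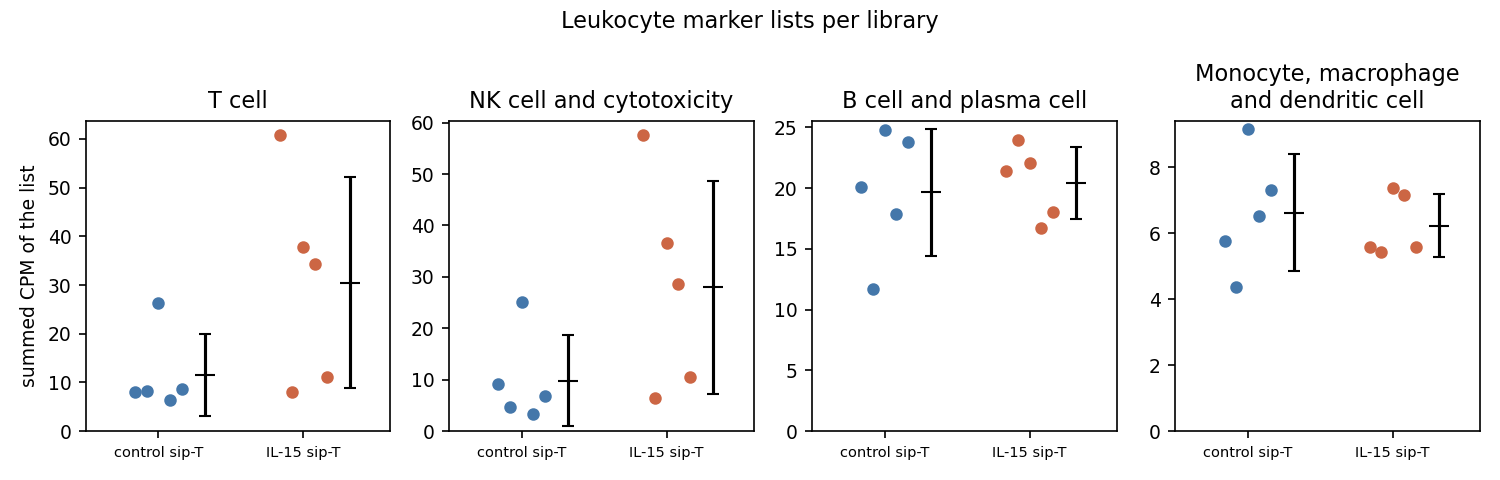
Summed CPM of 4 leukocyte marker lists (vertical axis, linear from 0) in each library (points) of the control and IL-15 sip-T groups, with mean and SD over 5 libraries in black. T cell sums of IL-15 tumours ran from 8.13 to 60.9 CPM and those of control tumours from 6.40 to 26.4 CPM.

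Genes of antigen presentation and interferon response had higher medians in IL-15 tumours. Of 20 tested MHC class I and antigen processing genes, 13 had fold changes above 0 and 7 below, with a median log2 fold change of 0.26 (camera adjusted p = 0.0397, and adjusted p = 0.744 with an estimated correlation). The immunoproteasome subunit genes PSMB9 and PSMB8 measured 0.754 ± 0.519 against 3.04 ± 2.56 CPM and 0.328 ± 0.333 against 1.197 ± 0.796 CPM. B2M, which encodes the light chain of MHC class I (ENSG00000166710, chromosome 15, 44711487 to 44718877), measured 185 ± 41.2 CPM in control tumours and 242 ± 31.7 CPM in IL-15 tumours (log2 fold change 0.38 ± 0.17). The classical class I gene HLA-B measured 27.7 ± 6.68 against 45.6 ± 18.7 CPM (log2 fold change 0.72 ± 0.31). HLA-E had a log2 fold change of 0.42 ± 0.24. Reads of HLA genes can be shared between their near-identical paralogs, so single HLA values are uncertain. Of 19 tested interferon gamma response genes, 13 were above 0 (median log2 fold change 0.21, camera adjusted p = 0.0308, and adjusted p = 0.744 with an estimated correlation). No member of either list passed edgeR over all genes or adjusted over the list alone.

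The MHC class I call held in 8 of 17 settings. It was lost with upper quartile scaling (camera adjusted p = 0.0505), library size alone (0.0595) or a minimum mean of 1 CPM (0.0767), and without control replicate 1, 2, 4 or 5 or IL-15 replicate 4 or 5 (up to 0.198). The interferon gamma call was lost without IL-15 replicate 3, 4 or 5, with camera adjusted p up to 0.0905. Of 24 tested type I interferon genes, 14 had fold changes above 0 and 10 below, among the latter IRF7 (34.6 ± 11.4 against 23.7 ± 3.08 CPM, log2 fold change -0.54 ± 0.20). The type I interferon list did not pass camera (adjusted p = 0.297), yet BST2, which encodes tetherin (ENSG00000130303, chromosome 19, 17402939 to 17405648), and OAS2, an antiviral oligoadenylate synthetase gene, passed edgeR adjusted over the list alone (0.0216 for each). BST2 measured 1.67 ± 0.518 CPM in control tumours and 4.54 ± 2.59 CPM in IL-15 tumours (log2 fold change 1.44 ± 0.37), and every IL-15 tumour lay above every control tumour. OAS2 measured 0.406 ± 0.297 against 1.78 ± 1.18 CPM (log2 fold change 2.11 ± 0.55). Neither BST2 nor OAS2 passed edgeR over all genes (adjusted p = 0.758 for each). The BST2 call was lost without control replicate 2, 3 or 5 or IL-15 replicate 4 (values up to 0.0758). The OAS2 call was lost without control replicate 1, 3 or 5 or IL-15 replicate 4 or 5 (up to 0.0869). All 4 tested MHC class II genes had fold changes above 0, among them HLA-DMA (3.56 ± 0.721 against 6.37 ± 2.62 CPM), with no member past the threshold adjusted over the list alone.

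Among prostate antigen genes, FOLH1 and KLK4 had lower values in IL-15 tumours. FOLH1, which encodes prostate-specific membrane antigen (ENSG00000086205, chromosome 11, 49146635 to 49208670), measured 729 ± 146 CPM in control tumours and 480.1 ± 53.1 CPM in IL-15 tumours (log2 fold change -0.60 ± 0.16, n = 5 per group). The kallikrein gene KLK4 (ENSG00000167749, chromosome 19, 50906352 to 50910738) measured 382 ± 78.1 CPM in control tumours and 254 ± 32.7 CPM in IL-15 tumours (log2 fold change -0.59 ± 0.16). For both genes every IL-15 tumour lay below every control tumour, and both passed edgeR adjusted over the list alone (0.0158 for each) but not over all genes (0.758 for each). A full separation of 5 against 5 has an exact permutation p of 0.00794, before any adjustment over the 16913 tested genes. Adjustment over the list alone was made for each of 40 lists without correction across them, and 5 lists held a member past it. Of these, the erythrocyte list had only 1 tested member, whose p was therefore not adjusted at all. The FOLH1 call was lost without control replicate 3 or IL-15 replicate 1 (adjusted values up to 0.0543), whereas KLK4 kept it with each library left out. ACPP, which encodes prostatic acid phosphatase, the antigen used to prepare sip-T (ENSG00000014257, chromosome 3, 132317367 to 132368298), measured 124 ± 46.1 CPM in control tumours and 174 ± 111 CPM in IL-15 tumours (log2 fold change 0.48 ± 0.39). KLK3, which encodes PSA, measured 4743 ± 1071 against 5584 ± 1336 CPM (log2 fold change 0.24 ± 0.20). The list as a whole had 10 members above and 5 below 0 and did not pass camera (adjusted p = 0.879).

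Of 40 androgen response genes, 30 had fold changes above 0, with a median log2 fold change of 0.13 (camera adjusted p = 0.0352, and adjusted p = 0.744 with an estimated correlation). STEAP4, a metalloreductase gene, measured 3.45 ± 4.67 against 21.4 ± 31.4 CPM and KLF4, a transcription factor gene, 29.0 ± 8.60 against 41.1 ± 9.12 CPM. The log2 fold changes of KLK2 (0.17) and TMPRSS2 (0.05) did not pass. The call was lost without control replicate 2, 3 or 5 or IL-15 replicate 2 or 4, with camera adjusted p up to 0.479.

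**Figure D2:**
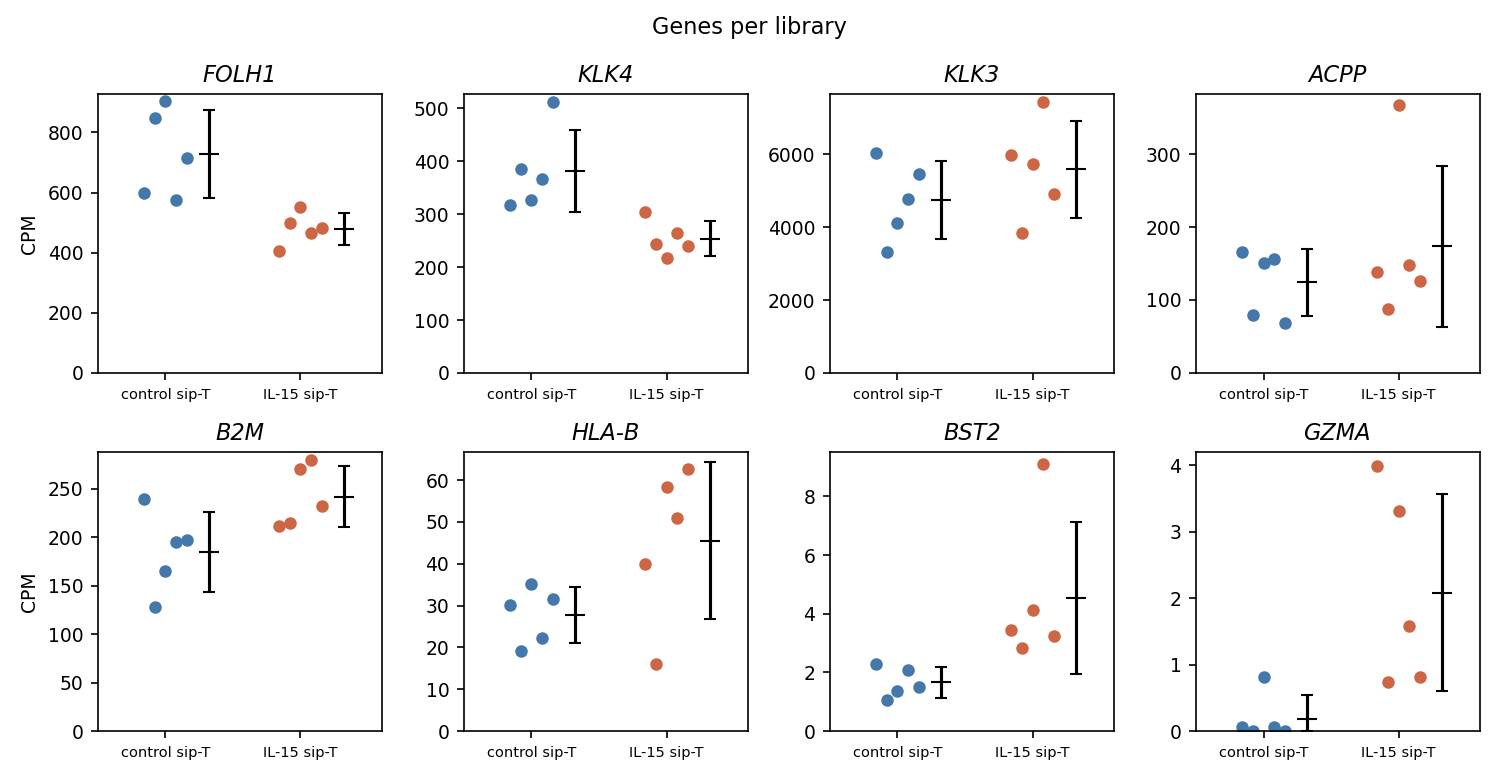
CPM (vertical axes, linear from 0) of 8 genes in each library (points) of the control and IL-15 sip-T groups, with mean and SD over 5 libraries in black, bars that would cross 0 ending there. FOLH1 and KLK4 were lower in every IL-15 library than in any control library, and ACPP had 1 IL-15 library at 367 CPM.

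All 29 ribosomal protein genes had fold changes below 0 in IL-15 tumours, and most hypoxia genes had fold changes above 0. The ribosomal list passed the test (median log2 fold change -0.27, camera adjusted p = 7.18e-09, and adjusted p = 0.744 with an estimated correlation), with RPS19 at 648 ± 144 against 453 ± 145 CPM and RPLP0 at 3995 ± 438 against 3179 ± 651 CPM. With the ratio of FPKM total to count total of each library as a covariate, chosen after the data were seen, the ribosomal median was -0.07 (camera adjusted p = 0.276). MYC target and ribosome biogenesis genes were below 0 for 18 of 22 members (median -0.15, camera adjusted p = 0.0308, and adjusted p = 0.871 with an estimated correlation), and with that covariate their median was 0.05. Of 27 hypoxia genes 22 were above 0 (median log2 fold change 0.26, camera adjusted p = 0.00364, and adjusted p = 0.804 with an estimated correlation), including the collagen prolyl hydroxylase genes P4HA1 (0.46 ± 0.22) and P4HA2 (0.61 ± 0.27). With the same covariate the hypoxia median was 0.60 (camera adjusted p = 6.29e-14, and adjusted p = 0.574 with an estimated correlation). The ratio is close to a scaling factor computed from the same counts and followed the first principal component (r = -0.93). The glycolysis list also went from a camera adjusted p of 0.970 to 2.82e-06 with it. Values with this covariate therefore decide nothing on the ribosomal, MYC or hypoxia lists. The hypoxia call was lost without control replicate 1 or IL-15 replicate 5 (adjusted p up to 0.231), and the MYC call without control replicate 2 or 5 or IL-15 replicate 3 or 4 (up to 0.689).

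Across all 16913 tested genes, edgeR's quasi-likelihood test found 0 genes with an adjusted p under 0.05 (smallest 0.758), and 1092 with an unadjusted p under 0.05, 512 higher and 580 lower in IL-15 tumours. DESeq2 called 15 genes, 12 higher and 3 lower (1683 at an unadjusted p under 0.05), and limma voom 0 (1095). The protein-coding genes with the smallest p per direction are therefore given as values. Among those higher in IL-15 tumours, STC1, a glycoprotein hormone gene (ENSG00000159167, chromosome 8, 23841915 to 23854807), measured 8.43 ± 3.42 CPM in control tumours and 22.8 ± 7.75 CPM in IL-15 tumours (log2 fold change 1.43 ± 0.30, DESeq2 adjusted p = 0.0166). The calcium-binding protein gene S100P measured 4.91 ± 1.51 against 16.8 ± 9.65 CPM (log2 fold change 1.77 ± 0.42, DESeq2 adjusted p = 0.0166). ADRB1, which encodes an adrenergic receptor, had a log2 fold change of 1.30 ± 0.30 and passed DESeq2 (adjusted p = 0.0389). IGIP had a log2 fold change of 1.17 ± 0.25 and passed DESeq2 as well (adjusted p = 0.0166). MNX1 (1.06), L3MBTL3 (0.95), PURA (0.89) and the decoy receptor gene TNFRSF10D (0.68) were also in this group and passed neither tool. IGIP and PURA lie close together on chromosome 5 (140125935 to 140129392 and 140107777 to 140125619). The antisense gene MALINC1, named after its value was seen, passed DESeq2 (adjusted p = 0.0129). It spans 140072857 to 140108630 and overlaps PURA, so these genes may not be separate results. VLDLR, a lipoprotein receptor gene in the stress response list, measured 37.3 ± 8.54 against 67.3 ± 14.97 CPM and passed edgeR adjusted over its list alone (0.0118).

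Among the genes lower in IL-15 tumours, the kinesin gene KIF26B measured 3.86 ± 1.47 against 1.31 ± 0.460 CPM (log2 fold change -1.54 ± 0.35, DESeq2 adjusted p = 0.0389). The small heat shock protein gene HSPB8 measured 8.12 ± 4.35 against 2.70 ± 0.834 CPM (log2 fold change -1.59 ± 0.39, DESeq2 adjusted p = 0.0485). OPLAH (-0.99), NFRKB (-0.60), ALPK3 (-0.77), TRIM5 (-0.80), CDH4 (-1.39), MAPK8IP1 (-0.52), PLEKHA7 (-0.45) and SIPA1L3 (-0.53) had smaller log2 fold changes and passed neither tool. NFRKB, TRIM5, MAPK8IP1 and PLEKHA7 lie on chromosome 11, as does FOLH1. Other genes there that the naming rule took were also lower, among them IRF7 (-0.54), STIP1 (-0.50), PNPLA2 (-0.49) and RPLP2 (-0.47). Of the tested genes that this rule took on that chromosome, CD44 alone was higher. Its level was low (0.727 ± 0.859 against 1.82 ± 1.81 CPM, log2 fold change 1.33 ± 0.87). Shifts by chromosome position were not tested. Of the 34 lists with at least 5 tested members, 9 passed camera with the preset correlation, 7 upward and 2 downward, and 0 with an estimated correlation or with limma's fry (smallest adjusted p = 0.657).

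**Figure D3:**
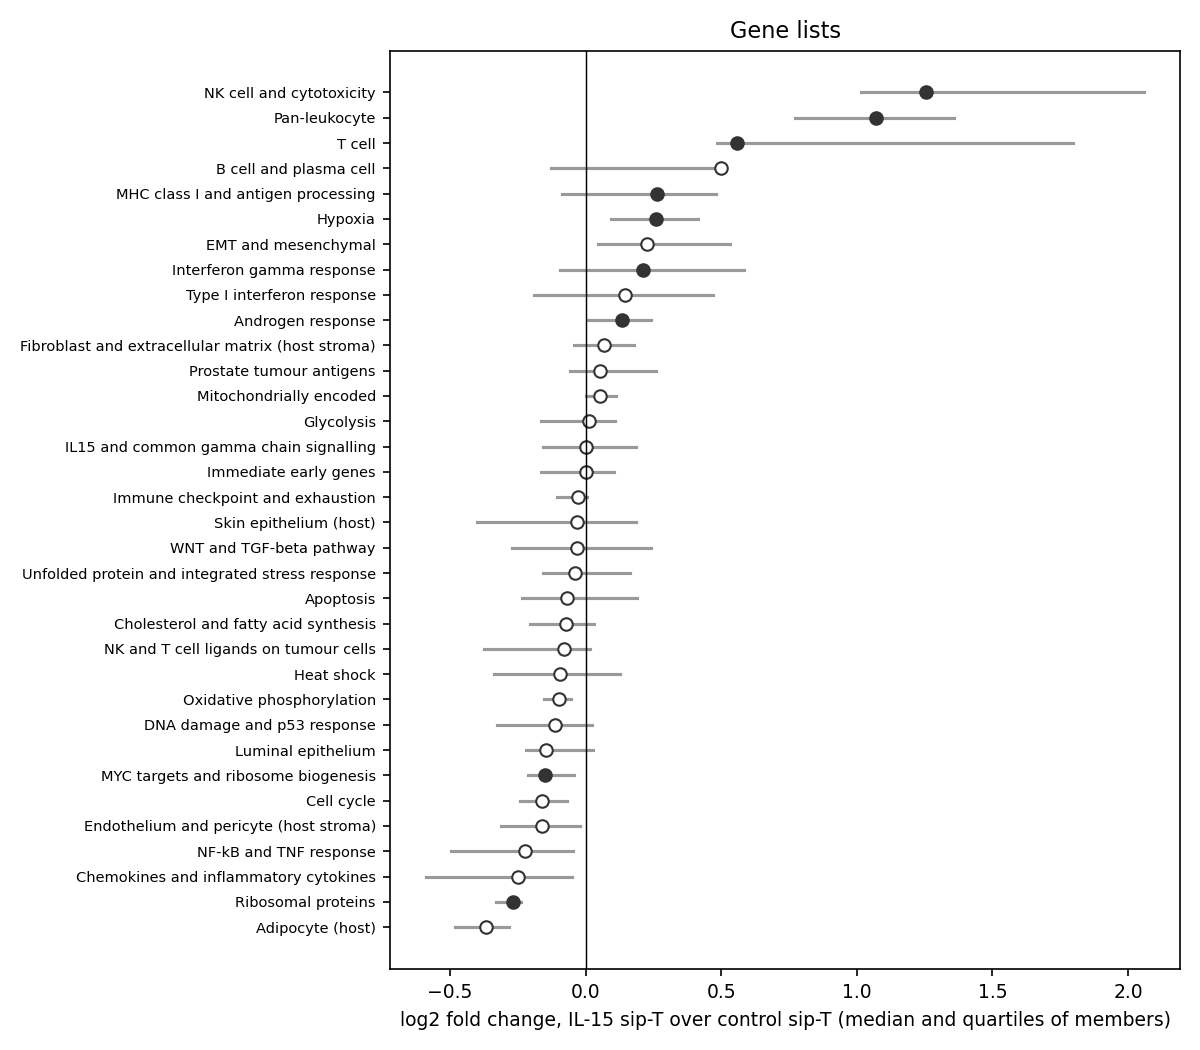
Median log2 fold change of IL-15 over control sip-T (horizontal axis) for the 34 gene lists tested, with grey lines from the lower to the upper quartile of members. Filled points mark the 9 lists with a camera adjusted p under 0.05 at the preset correlation, none of which passed with an estimated correlation.

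The remaining 25 lists had camera adjusted p-values from 0.0516 to 0.994. Oxidative phosphorylation genes were below 0 for 20 of 22 members (median -0.10) and cell cycle genes for 28 of 34 (median -0.16), with MKI67 at 151 ± 41.6 against 132 ± 22.3 CPM. In the immune checkpoint list, LAG3, an inhibitory receptor gene, measured 2.82 ± 0.972 against 5.81 ± 2.67 CPM (log2 fold change 1.04 ± 0.35), CD274, which encodes PD-L1, 0.800 ± 0.311 against 0.682 ± 0.331 CPM, and CD276 140 ± 22.9 against 140 ± 17.1 CPM. In the IL-15 signalling list, IL15RA, the private receptor chain of IL-15, measured 2.12 ± 1.03 against 0.958 ± 0.359 CPM (log2 fold change -1.14 ± 0.37). Of 14 tested genes for ligands of NK and T cells, 5 had fold changes above 0 and 9 below. The stress ligand gene ULBP2 measured 3.84 ± 0.814 against 6.52 ± 2.39 CPM, MICA 12.2 ± 1.94 against 12.4 ± 3.01 CPM and TNFRSF10A 20.9 ± 3.44 against 15.6 ± 3.32 CPM. None of the genes named in this paragraph passed edgeR over all genes or adjusted over its list alone.

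The first principal component of the 500 most variable genes held 34.9% of the variance and followed the ratio of FPKM total to count total of each library (Pearson r = -0.93, permutation p = 5e-05, adjusted 2.75e-04, Spearman rho = -0.95, permutation p = 1.2e-04, adjusted 0.00132, 11 relations over 10 libraries). Without the 2 libraries farthest from the median ratio, r was -0.92. Within control and IL-15 libraries r was -0.94 and -0.89 (5 libraries each, values only). The ratio is itself close to a scaling factor computed from the counts, as it differed from the DESeq2 size factor per count by a constant and a further factor of 0.987 to 1.01. For the TMM factor, by which the CPM were scaled, that further factor was 0.981 to 1.025. The relation of the component to the ratio may therefore be partly built in, which its permutation p does not exclude. The ratio averaged 1.07 ± 0.06 in control and 1.14 ± 0.07 in IL-15 libraries (exact permutation p = 0.103, adjusted 0.512, n = 5 per group).

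**Figure D4:**
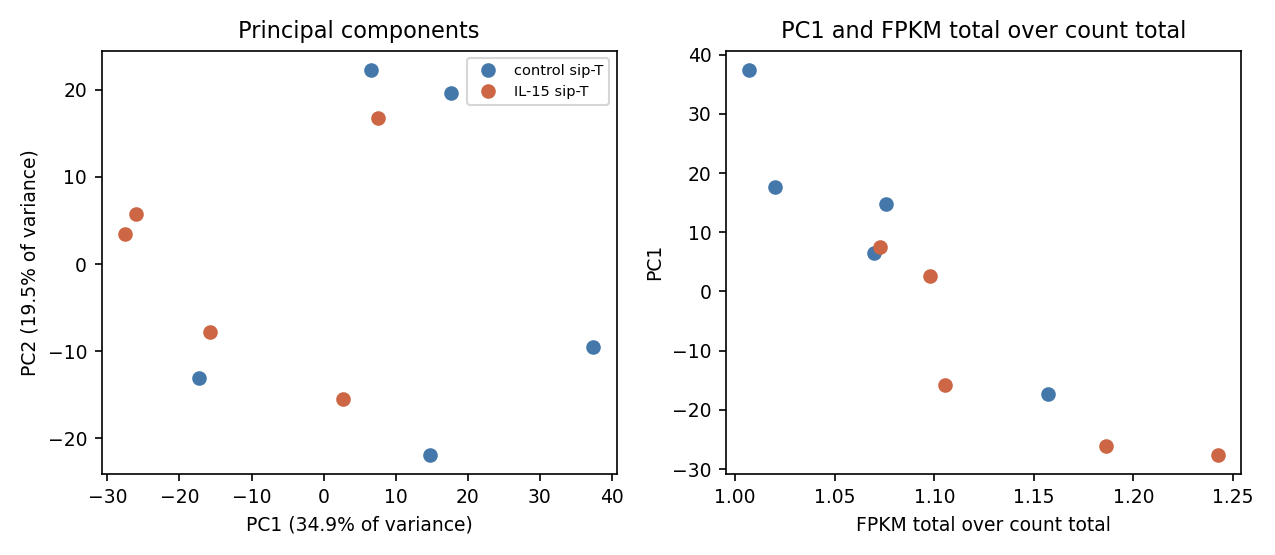
Left, the first and second principal components of log2 CPM (unitless) for each library, coloured by group. Right, the first component against the ratio of the FPKM total to the count total (unitless), along which libraries of both groups followed a descending line (r = -0.93).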

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

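Among 102 sets of 5 library values checked for a single distant library, 7 had one, where chance gives about 1 in 20. The tests on GNLY and TRAC, on the T cell sum, on leukocyte amount, on MHC class I with the T cell sum and on the ribosomal covariate were chosen after the results were seen, whereas those on receptor genes, on the pan-leukocyte sum with a covariate, on the other MHC class I covariates and on the most abundant genes were set before their own results were seen. All covariates were added after the data had been seen. The tests on receptor genes, on the pan-leukocyte sum and on the other MHC class I covariates were for a time replaced by versions chosen after their values were seen, and were then restored as first set, which weakens their standing.

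Control tumour 3 stood above the other control tumours for the T cell list (26.4 CPM against 6.40 to 8.72), the NK cell and cytotoxicity list (25.2 CPM against 3.26 to 9.22) and CD8A (4.17 CPM against 0.572 to 1.55). ACPP stood at 367 CPM in IL-15 tumour 3 and between 87.7 and 148 CPM in the other IL-15 tumours. IGIP stood at 8.71 CPM in control tumour 1, against 4.79 to 5.64 CPM in the other control tumours. CDH4 stood at 1.10 CPM in control tumour 4, against 2.18 to 2.26 CPM. IL-15 tumour 2 had the largest total count of its group, 19.3 in units of 1e+06 reads, against 13.6 to 14.6.

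For the higher leukocyte markers of IL-15 tumours, the planned test asked whether reads of mouse cells had been assigned to human genes. Summed T cell receptor V and J genes did not follow the T cell list (Spearman rho = 0.12, permutation p = 0.758), as mouse reads would give, but 49.8% of those counts, as found afterwards, fell on gamma chain genes, which prostate cells also transcribe, so this test leaves them open. In a second test, chosen after that result, GNLY, a gene with no symbol in the mouse annotation, followed the T cell list closely (rho = 0.92, permutation p = 5.10e-04, r = 0.91 without the 2 farthest libraries), which argues, from 1 gene, against mouse reads as the whole source. The alpha constant gene TRAC had 44 counts in control tumour 3 and 90, 41 and 36 in IL-15 tumours 1, 3 and 4, against 1 to 6 elsewhere, which goes the same way but is partly built in, since TRAC belongs to the T cell list. The host strain has no T, B or NK cells of its own, so host lymphocytes are not a likely source of such reads. Reads of other mouse cells are not excluded by this. With the ratio of FPKM total to count total as a covariate, the log2 difference of the pan-leukocyte sum went from 1.32 ± 0.60 to 0.80 ± 0.68 and that of the T cell sum from 1.23 ± 0.66 to 0.90 ± 0.81, while the T cell and NK lists kept medians of 0.62 and 1.03 (camera adjusted p = 0.0448 and 0.00455, and adjusted p = 0.574 with an estimated correlation for each), but the ratio counts no reads, so a differing share of reads outside genes stays untested, and more human leukocytes or T cells may account for the pattern (adjusted exact permutation p = 0.238 for each sum, n = 5 per group).

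For the higher MHC class I list, RNA of infiltrating leukocytes is a candidate explanation. With the first covariate tried, the pan-leukocyte sum, the median log2 fold change went from 0.26 to 0.15 (camera adjusted p = 0.362), short of the reduction set in advance, and with the T cell sum, tried afterwards because LCP1 makes up most of the pan-leukocyte sum, it went to 0.11 (camera adjusted p = 0.571). The errors of the group difference over libraries were 0.21 and 0.18 with these covariates, larger than the drops, so neither value decides. With the ratio of FPKM total to count total as a covariate the median log2 fold change stayed at 0.22 (camera adjusted p = 0.00821, and adjusted p = 0.574 with an estimated correlation), with an error of 0.21 for the group difference over libraries. That value met the bound set in advance against a differing share of reads outside genes, but the ratio was found afterwards to be no count of reads, so it decides nothing on that share, which remains open.

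For the lower ribosomal protein list, with the ratio of FPKM total to count total as a covariate the median log2 fold change went from -0.27 to -0.0655 (camera adjusted p = 0.276), with a standard error of 0.15 for the group difference, which, the ratio being no count of reads, leaves a differing share of reads outside genes open. This was not particular to that covariate, as the median was -0.05 with the pan-leukocyte sum (camera adjusted p = 0.402) and -0.10 with the T cell sum (0.0896). The mean level of the list fell with the ratio across libraries (r = -0.81, permutation p = 0.00418, adjusted 0.0153, rho = -0.65, permutation p = 0.0480, adjusted 0.0769), but r was -0.44 without IL-15 tumours 1 and 3, on which the relation rests. The ratio also follows the TMM factor by which the CPM were scaled, so part of this relation may be built in, and the permutation p does not exclude that. For a few genes taking most of the counts, the planned test asked for a share of the 10 most abundant genes higher in every IL-15 library than in every control library. The share overlapped between groups (the lowest IL-15 value lay -1.27 percentage points from the highest control value). Its mean was 7.55% in control and 7.91% in IL-15 libraries (exact permutation p = 0.341, adjusted 0.512). Overlap does not exclude a smaller shift, so this explanation stays open. A biological difference in ribosomal transcripts was not tested.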

How the results depend on the processing

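Results with covariates, a changed pseudocount for the sums or members under 1 CPM were chosen after the data had been seen. The count of 0 genes by edgeR held under the other scalings, a minimum mean of 1 CPM, protein-coding genes alone, limma on counts or FPKM and each library left out (0 to 0 genes). It became 1 with no filter on low counts (MALINC1, edgeR adjusted p = 0.00632, a gene named after its value was seen) and 15 with DESeq2. The cause was not tested. The number of genes at an unadjusted p under 0.05 ran from 616 without IL-15 replicate 3 to 1575 without IL-15 replicate 2, and was 388 with the ratio of FPKM total to count total as a covariate, 2756 with no filter, 1826 by limma with quality weights and 1683 by DESeq2. Their split moved from 512 higher and 580 lower to 629 and 422 with upper quartile scaling and to 768 and 324 with library size alone. Of the gene lists, 9 passed in the main test, 8 to 12 with 1 library left out, 3 with library size alone, 10 with that ratio as a covariate, 2 with the pan-leukocyte covariate, 4 with the T cell covariate, and 0 with an estimated correlation or with fry, whose own construction allows for correlated members. With library size alone the T cell, pan-leukocyte, interferon gamma, MHC class I, androgen and MYC lists were lost (camera adjusted p = 0.0595 for each), and the MYC list also with protein-coding genes alone (0.0538). With the ratio as a covariate the pan-leukocyte (camera adjusted p = 0.366), ribosomal (0.276) and MYC (0.301) lists were lost, while the glycolysis (from 0.970 to 2.82e-06), adipocyte (0.00821), mitochondrially encoded (0.0415) and cholesterol and fatty acid synthesis (0.0392) lists newly passed. None of these 4 held there with an estimated correlation (adjusted p = 0.574, 0.469, 0.685 and 0.685 with an estimated correlation). The MYC list changed direction with the ratio or the pan-leukocyte sum (0.217) as a covariate, and the cholesterol list with the ratio. The cause was not tested. With 1 library left out, the log2 difference of the summed lists ran from 0.89 to 1.61 for T cells, 1.11 to 1.90 for NK cells, 0.96 to 1.65 for the pan-leukocyte list, -0.08 to 0.18 for B cells and -0.20 to 0.07 for monocytes, and none passed after adjustment under any alternative. Without control replicate 5, the endothelial list reached the smallest exact permutation p, 0.00794, yet 0.0952 after adjustment. Not passing therefore says little on how stable these sums are. As means of members' log2(CPM + 1), the T cell, NK and pan-leukocyte differences were 0.48, 0.36 and 0.77, and over members under 1 CPM over all libraries 1.46, 0.73 and 2.44, with -0.97 for B cells. Choosing the members by the control libraries alone, which favours higher values in the IL-15 group, gave 1.41, 1.38 and 2.35. Samples with the same replicate number showed little common deviation (correlations 0.26, 0.01, -0.17, -0.22 and -0.08), and only those numbered 1 correlated best with their own number. So few values cannot exclude pairing, and the labels do not say what a number marks. With the replicate number as a block, edgeR called 0 genes, 10 lists passed, and the T cell, NK and pan-leukocyte sums had an adjusted permutation p of 0.375, in a test whose smallest unadjusted p is 0.0625. Of 4368 values of named genes under alternatives, 65 had the opposite sign, none past the threshold. At these depths a 2-fold change was recovered for 33% and a 4-fold change for 93% of 100 simulated genes each. Those genes were picked at random and drawn without shared variation, so the recovery need not hold for scarce, variable genes.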

Other observations

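The tests of how often other groupings of the libraries gave as much were planned for the unadjusted and list counts and added afterwards for the adjusted count. Host tissue lists showed no difference past adjustment, with fibroblast and matrix genes at 1306 ± 407 against 1149 ± 173 CPM, endothelial and pericyte genes at 195 ± 34.9 against 164 ± 9.41 CPM, and adipocyte genes at 151 ± 41.99 against 113 ± 44.4 CPM (SD, n = 5 each). The largest members, FN1, NOTCH3 and PNPLA2, made up 51.7%, 37.9% and 63.7% of these sums. The values count reads assigned to human genes, so the sums cannot tell host tissue from tumour cells and do not measure its amount. The erythrocyte list, of which SLC25A37, a mitochondrial iron importer gene, made up 99.8%, stood at 179 ± 29.2 against 239 ± 27.6 CPM (log2 difference 0.43 ± 0.13, exact permutation p = 0.0159, adjusted 0.190, n = 5 per group). SLC25A37 was the only member tested, so its edgeR p of 0.0103 was left unchanged by adjustment over the list alone.

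Of 15 heat shock genes, 7 had fold changes above 0 and 8 below (camera adjusted p = 0.231). Those below 0 included STIP1, a co-chaperone gene, at 265 ± 52.3 against 187 ± 16.3 CPM and HSPA4L at 20.3 ± 13.99 against 7.74 ± 3.02 CPM. The differentiation inhibitor gene ID2 measured 5.10 ± 0.894 against 10.1 ± 3.85 CPM (log2 fold change 0.98 ± 0.28). None of them passed edgeR over all genes or adjusted over its list alone. The genes in the rest of this paragraph were chosen after their values were seen. The immunoglobulin light chain gene IGKC had 72 counts in control tumour 3 and 0 in each other library, and IGHG1 had 61 counts there and at most 3 elsewhere. The T cell receptor alpha constant gene TRAC had 44 counts in control tumour 3 and 90, 41 and 36 in IL-15 tumours 1, 3 and 4, against 1 to 6 in the other libraries. The beta constant gene TRBC1 had 21 counts in control tumour 3 and 45, 18 and 15 in the same IL-15 tumours, against 0 to 4 elsewhere. TRBC2 had 13 counts in control tumour 3 and 17, 32 and 28 in those IL-15 tumours, against 0 to 6 elsewhere. TRGC1, a gamma constant gene, had 17 counts in control tumour 3 and 100 to 572 in the other control tumours, and 378, 443 and 630 counts in IL-15 tumours 1, 3 and 4, with 403 and 103 in IL-15 tumours 2 and 5.

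Of 4 relations of the T cell or pan-leukocyte list with MHC class I or interferon gamma genes across the 10 libraries, none passed 0.05 after adjustment by Pearson's r. The T cell list and the mean of MHC class I genes had the highest coefficients (r = 0.68, permutation p = 0.0374, adjusted 0.0846, rho = 0.78, permutation p = 0.0113, adjusted 0.0398 over 11 relations), with r = 0.73 without the 2 farthest libraries, 0.86 within control and 0.37 within IL-15 libraries. The libraries left out were IL-15 tumours 1 and 3. The value within control libraries includes control tumour 3, whose T cell sum was 26.4 CPM against 6.40 to 8.72 CPM in the others, and was not computed without it. The pan-leukocyte list and MHC class I genes had r = 0.54 (permutation p = 0.114, adjusted 0.156) and rho = 0.65 (permutation p = 0.0489, adjusted 0.0769), with r = 0.47 without the 2 farthest libraries. For interferon gamma genes, r was 0.66 with the T cell list (permutation p = 0.0456, adjusted 0.0846, rho = 0.61, permutation p = 0.0667, adjusted 0.0917) and 0.56 with the pan-leukocyte list (permutation p = 0.0953, adjusted 0.150, rho = 0.75, permutation p = 0.0181, adjusted 0.0398), and without the 2 farthest libraries 0.79 and 0.38. Within control and IL-15 libraries, r with the T cell list was 0.97 and 0.30, and with the pan-leukocyte list 0.31 and 0.50. LCP1 made up 94.2% of the pan-leukocyte sum.

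Chance could not be excluded for the count of genes at an unadjusted p under 0.05 or for the count of lists. Of 100 splits of the 10 libraries into 5 and 5, drawn from 126 and including the real one, 22 gave at least the real 1092 genes (highest other 2841) and 25 at least the 9 lists (highest other 13). For the edgeR count of 0 the test decides nothing, since all 100 splits give at least 0 (highest other 101). The split with 101 genes set control tumour 1 and IL-15 tumours 1, 3, 4 and 5, the libraries with the highest ratios of FPKM total to count total (1.10 to 1.24), against the rest (1.01 to 1.08). This split was picked because it had the highest count, and it keeps most IL-15 tumours on 1 side. The ratio is close to a scaling factor computed from the same counts, so it is no separate evidence of a structure of the samples. What gave the 101 genes was not tested.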
